A study of Mus musculus with 3 samples.

How the data were processed

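Total RNA from F9 cells, a mouse embryonal carcinoma line that stays undifferentiated in ordinary culture, was measured on 3 Affymetrix Mouse Genome 430 2.0 arrays, 1 for each labelled replicate. Per the labels' protocols, the cells grew on plates coated with 0.2% gelatin in medium with 10% serum, were harvested near 80% confluence, and RNA was extracted with Trizol and biotin-labelled by the array maker's standard procedure. All 3 samples form 1 group. No treated, differentiated or other reference sample belongs to the design, so no comparison between groups was possible, and the data were analysed for what lies above background and for the spread between arrays.

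The deposited values are linear signal intensities, 1 per probe set and array, with 45101 probe sets per array, of which 64 are Affymetrix controls. The authors used GCOS 1.4, the array maker's software, per the submitters' processing notes. The algorithm that turned probe brightness into a probe set signal, the software's present and absent calls, and any aligned genome build are not given in the sources used here. The deposited intensities themselves show that each array had been scaled: after trimming 2% of probe sets at each end, the mean signal was 249.9 on every array. No further normalization was applied. Scaling to a common mean hides any change in total RNA per cell, and signals of different probe sets depend on probe affinity, so levels were compared between arrays and with background, not between genes.

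Gene symbols came from a platform annotation of 2016. Of the probe sets other than controls, 34945 had a single gene symbol, 932 had several and 9160 had none; the last 2 kinds name no gene here. Gene identifiers of 34754 single-symbol entries were found in a GRCm38.p6 gene table, which changed 0 symbols. No genome coordinates are given, since the values carry no build. A gene with several probe sets was represented by the one with the highest mean signal over the arrays, giving 18193 named genes. Of the 9010 genes with several probe sets, 3598 (39.9%) had probe sets on both sides of the background call, so the choice of probe set matters.

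Background was measured on the arrays with 126 probe sets for 112 genes of families with narrow expression: olfactory, vomeronasal and taste receptors and hair keratin-associated proteins. Each array's threshold was the 95th percentile of these signals. For every probe set, log2 signal minus log2 threshold was tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, one-sided against 0), with Benjamini-Hochberg adjustment over all probe sets and an adjusted p threshold of 0.05. A gene that did not pass is called not above background, which does not mean absent. The labels do not say whether the 3 RNA samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

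Fixed before the data were examined were 27 gene lists, the test of each list, the alternatives and the rule for naming genes. The lists cover pluripotency states, the lineages F9 cells can enter, cell types that might contaminate a culture, cell functions, and adult tissues as negative lists. The share of a list above background was compared with that of all other named genes outside the background families by Fisher's exact test (two-sided), adjusted by Benjamini-Hochberg over the 27 lists. Genes are not independent replicates, so these tests describe the lists on these arrays. Each list was also set against 10000 random lists matched on the number of probe sets per gene. The naming rule took the first 4 measured members of each list in their written order, all members of the core, naive, primed and retinoid lists, and up to 3 members, alphabetically first, whose call differed from most of their list. For the spread between arrays it took the 10 genes above background with the largest range. Genes named outside that rule are marked as chosen after their values were seen.

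The calls were tested on simulated arrays with the real means and signal-dependent noise, over all 45101 probe sets. Of 200 probe sets set 1 log2 unit above the threshold, 80.5% were called, against 13% at 0.5 units, 100% at 2 units and 0% at the threshold itself. The noise was added to means that already hold noise, and the threshold was estimated again on the simulated arrays. Probe sets set at 0, 0.5, 1 and 2 units had median fitted values of -0.083, 0.36, 0.84 and 1.86. The shares called therefore belong to probe sets lying somewhat lower than set, those at 0 below the simulated threshold. Of 200 random lists of 16 genes, 2% had an unadjusted Fisher p under 0.05. Another 200 lists were built with 14 of 16 members above background, and 100% had such a p. Those lists all share the same counts and so the same p, which makes the 100% a single outcome and no measure of power.

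The alternatives were thresholds at the 90th and 99th percentiles, and olfactory receptors alone or the array median as background. They also covered an offset of 16 added to signal and threshold before the log, quantile normalization, and a probe set chosen by its suffix. Probe sets ending in _s_at or _x_at, which may cross-hybridise, were removed, or all 3 arrays had to lie above the threshold. Each replicate was also left out in turn. A background from the arrays' bacterial control probe sets, and the spread over all genes with mean log2 signal over the threshold, were added after the data were seen. Spread was summarised as the SD of log2 signal over the arrays, and 3' to 5' ratios of the Gapdh, beta-actin, transferrin receptor and pyruvate carboxylase control transcripts were taken per array. Every value column belonged to a labelled sample.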

Results

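The series holds 3 replicate arrays of undifferentiated F9 embryonal carcinoma cells, and the question it can answer is which genes these cells express. Each array measured 45101 probe sets. The median signal was 37.8, 37.8 and 36.0 on replicates 1, 2 and 3. The background threshold lay at a signal of 44.6 on replicate 1, 46.1 on replicate 2 and 42.0 on replicate 3, with bootstrap 95% intervals of 37.0 to 49.7, 38.9 to 53.7 and 30.7 to 48.0. Values below are mean signals ± SD over the 3 arrays (n = 3), and log2 values are relative to the threshold.

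About as many genes were above background as were not: 9253 of 18081 named genes (51.2%) passed limma's moderated test with Benjamini-Hochberg adjustment. Without a test, 9740 genes exceeded the threshold on all 3 arrays. Among the 112 background genes 1 was called, a low count fixed by construction because they set the threshold. In the adult photoreceptor, lymphocyte, muscle, liver and synaptic neuron lists together, 9 of 71 genes (12.7%) were called. The lists of core and naive pluripotency, the cell cycle, glycolysis and ribosomal proteins were above background in all their measured members, and the mesoderm and liver enzyme lists in none.

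**Figure D1:**
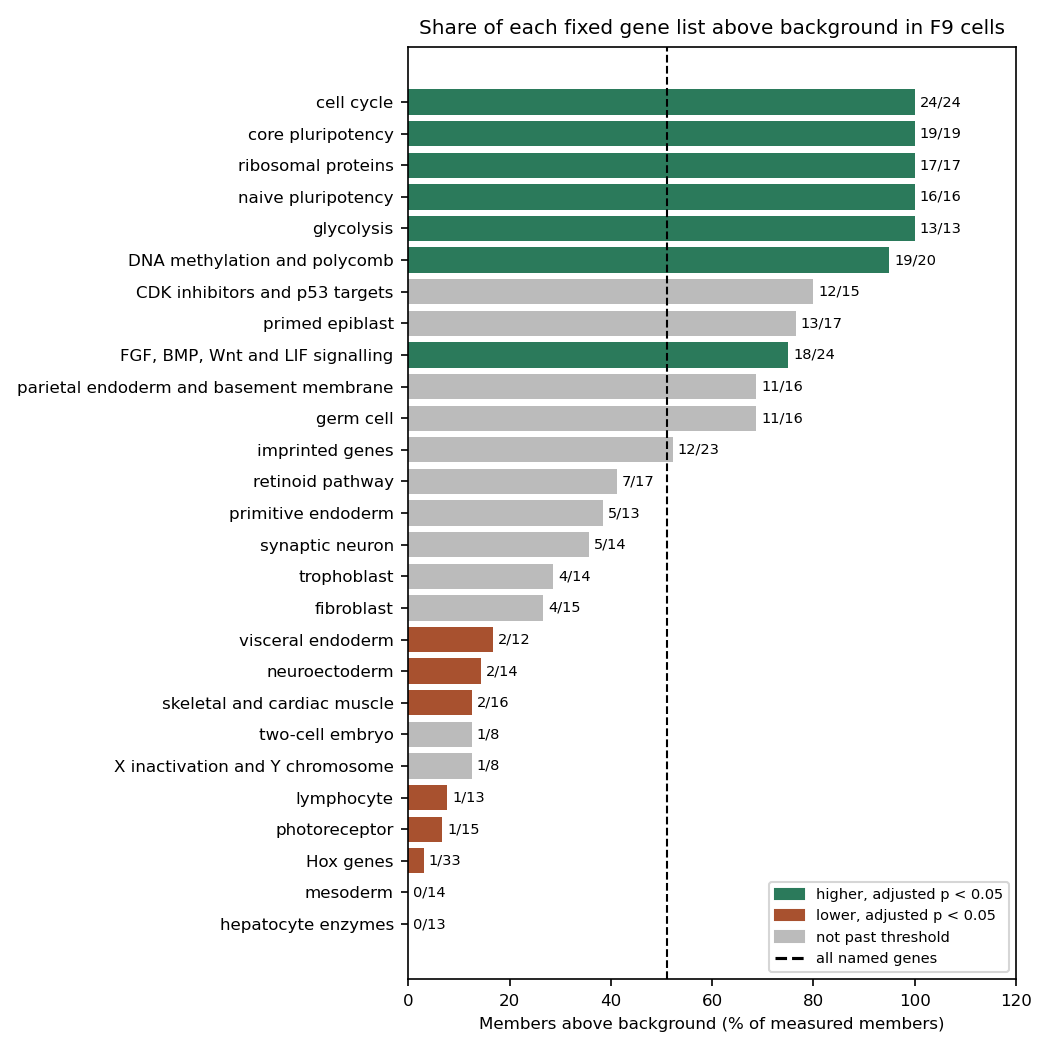
Horizontal bars give the percent of each fixed list's measured members above background, with the counts beside them; the dashed line marks the 51.2% of all named genes. Green bars lay above and brown bars below the other genes (Fisher's exact test, adjusted over 27 lists), and grey bars did not pass; Hox genes stood at 1 of 33 and the cell cycle list at 24 of 24.

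The core pluripotency genes were above background without exception, 19 of 19 measured. Pou5f1, which encodes the Oct4 transcription factor, had a signal of 6809 ± 279, 7.27 log2 units over the threshold. Its partner Sox2 stood at 4794 ± 208 and Nanog, another factor of the same network, at 4866 ± 392. Utf1 had a signal of 3183 ± 430, Sall4 of 3467 ± 231, Zfp42 (Rex1) of 6137 ± 128, and Dppa5a of 17712 ± 507. Esrrb, an orphan nuclear receptor, reached 2765 ± 218, and Fgf4, the growth factor secreted by pluripotent cells, 1884 ± 145. Lin28a, which blocks let-7 maturation, stood at 1912 ± 168. Trim71 had a signal of 1082 ± 167. The share exceeded the 51.1% of other genes (Fisher's exact test, adjusted p = 3.73e-05). Against random lists matched on probe sets per gene the adjusted p was 0.00108. The number of random lists, 10000, limits how small that p can be, so it is not comparable with Fisher's.

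Naive pluripotency genes, a list named for the state of the preimplantation epiblast, were also above background in 16 of 16 measured members (Fisher's exact test, adjusted p = 0.000168). No sample of another cell state was measured, so the share does not show that the members are particular to that state. The Krüppel-like factors Klf4 (1122 ± 70.9), Klf2 (3012 ± 409) and Klf5 (9634 ± 1386) were among them, as were Tfcp2l1 (3779 ± 83.7), Nr0b1 (6158 ± 325) and Tbx3 (1882 ± 152). Lifr, the receptor for leukaemia inhibitory factor, had a signal of 548 ± 131, and its co-receptor Il6st of 440 ± 40.7. Prdm14 stood at 467 ± 40.7. Dppa3 (Stella) lay 1.14 log2 units over the threshold at 98 ± 10.8 (limma adjusted p = 0.0051), and lost its call at the 99th percentile (0.0553). With the probe set chosen by suffix, the list was no longer above background throughout. Among the members named here, Klf5 and Tbx3 then lay below the threshold (-0.11 and -0.17 log2 units) and Lifr lost its call (0.19).

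Primed epiblast genes, a list named for the postimplantation state, were mixed, with 13 of 17 above background. Above background were the Nodal pathway members Nodal (1347 ± 96.1), Lefty1 (2619 ± 233) and Lefty2 (1186 ± 34.9), the de novo DNA methyltransferase Dnmt3b (1236 ± 99.2), Igfbp2 (5609 ± 476), and the transcription factors Otx2 (406 ± 54.7), Foxd3 (360 ± 46.7) and Pou3f1 (275 ± 36.5). Fgf5 (29.1 ± 5.58), Cer1 (11.7 ± 14.2), Zic2 (20.6 ± 13.7) and Wnt8a (22.7 ± 7.61) were not. The share was not past the threshold against other genes (Fisher's exact test, adjusted p = 0.071). Without replicate 1 the adjusted p of that test was 0.0447, and the list also passed against random lists matched on probe sets per gene. With Fisher's exact test on the naive and primed lists, the difference of 23.5 percentage points had p = 0.103, and the odds ratio's 95% interval began at 0.671. It became 29.4 points (exact p = 0.0445) without replicate 2 or without replicate 3, and 4.41 points (exact p = 1) with the probe set chosen by suffix.

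**Figure D2:**
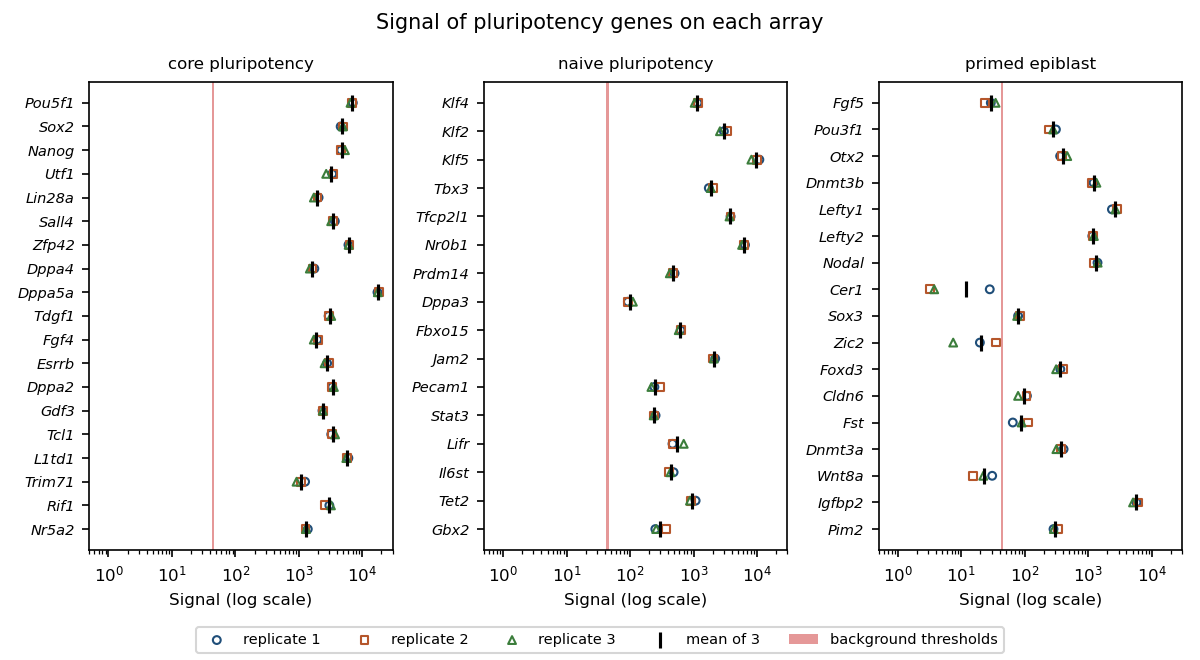
Each row is a gene and each open symbol its signal on 1 array (log scale), with a black tick at the mean of the 3 arrays and a red band over the background thresholds (42.0 to 46.1). All core and naive genes have means right of the band, Dppa3 at 98, while Fgf5, Cer1, Zic2 and Wnt8a have means left of it.

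F9 cells can be turned into primitive, parietal or visceral endoderm, so the 3 endoderm lists show how far such genes were expressed before any induction. The parietal list had 11 of 16 members above background, the primitive list 5 of 13 and the visceral list 2 of 12. The laminin chains Lama1 (420 ± 46.2), Lamb1 (250 ± 18.9) and Lamc1 (714 ± 80.3) and the collagen IV chain Col4a1 (1870 ± 374) passed. Sparc (3527 ± 356) and Nid1 (1143 ± 60.9), chosen after their values were seen, also passed. In the parietal list Krt18 (49.3 ± 9.64), Krt19 (12.1 ± 13.7) and Plat (27.4 ± 15.2) were not (Fisher's exact test, adjusted p = 0.249). In the primitive list the number was 8 when adjusted over the list alone, and the share did not differ past the threshold from other genes (Fisher's exact test, adjusted p = 0.447). Sox7 stood clear at 889 ± 106, though only 1 of its 2 probe sets was above background. Gata4 (52.8 ± 17.7) and Sox17 (69.7 ± 18.6) did not pass. Gata6 (57.5 ± 3.95) passed at 0.38 log2 units with a limma adjusted p of 0.049. Its call was lost when any 1 replicate was left out (limma adjusted p from 0.119 to 0.215), and it lay at -0.022 log2 units at the 99th percentile. Hhex (162 ± 11.7) and Amn (86.9 ± 11.5) passed.

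Of the visceral endoderm list, 2 of 12 were above background: Apoe (3368 ± 185) and the transferrin receptor gene Tfrc (5352 ± 210), which many cell types express. Afp (16.8 ± 20.2), Ttr (24.4 ± 10.4), Hnf4a (50.4 ± 9.65) and Apoa1 (14.3 ± 20.1) were not. The share was below that of other genes (Fisher's exact test, adjusted p = 0.0381), and the call was lost when any 1 replicate was left out (adjusted p from 0.0602 to 0.0666, with the same 16.7%), at the 99th percentile (adjusted p = 0.072), with the probe set chosen by suffix (0.121), or with the lower threshold from bacterial controls, chosen after the data were seen (33.3%, adjusted p = 0.121). Core pluripotency genes exceeded the union of the endoderm lists, 18 of 41 above background, by 56.1 percentage points (Fisher's exact test, p = 9.61e-06). The union's share of 43.9% lay near the 51.2% of all named genes, and the core list stood at its ceiling of 100%. The difference thus mainly reflects the core list and does not show that endoderm genes were low.

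The retinoid pathway, which carries the retinoic acid signal used to differentiate F9 cells, was split, with 7 of 17 measured members above background (Fisher's exact test, adjusted p = 0.49). Receptor genes above background were Rarg (1397 ± 201), Rxrb (452 ± 54.1), Rara (134 ± 34.7) and Rxra (133 ± 48.0). Rarb (15.4 ± 12.9) and Rxrg (26.3 ± 25.1) were not above background. The same held for the retinoic acid degrading enzymes Cyp26a1 (36.7 ± 22.3) and Cyp26b1 (16 ± 8.01), the retinol receptor Stra6 (8.24 ± 0.771), and the retinaldehyde dehydrogenases Aldh1a1 (6.44 ± 5.81), Aldh1a2 (48.9 ± 15.3) and Aldh1a3 (26.05 ± 15.2). Of the binding proteins, Fabp5 (1695 ± 98.1) and Crabp2 (75.2 ± 9.93) passed and Crabp1 (58.7 ± 15.1) did not. Rdh10, a retinol dehydrogenase, stood at 197 ± 33.9, and Dhrs3 at 51.8 ± 3.57 did not pass. Rxra lost its call without replicate 1 (limma adjusted p = 0.0656) and Crabp2 without replicate 1 or replicate 2 (0.0681 and 0.061). With the probe set chosen by suffix Rxra lay at -2.97 log2 units and Rdh10 lost its call at 0.11.

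**Figure D3:**
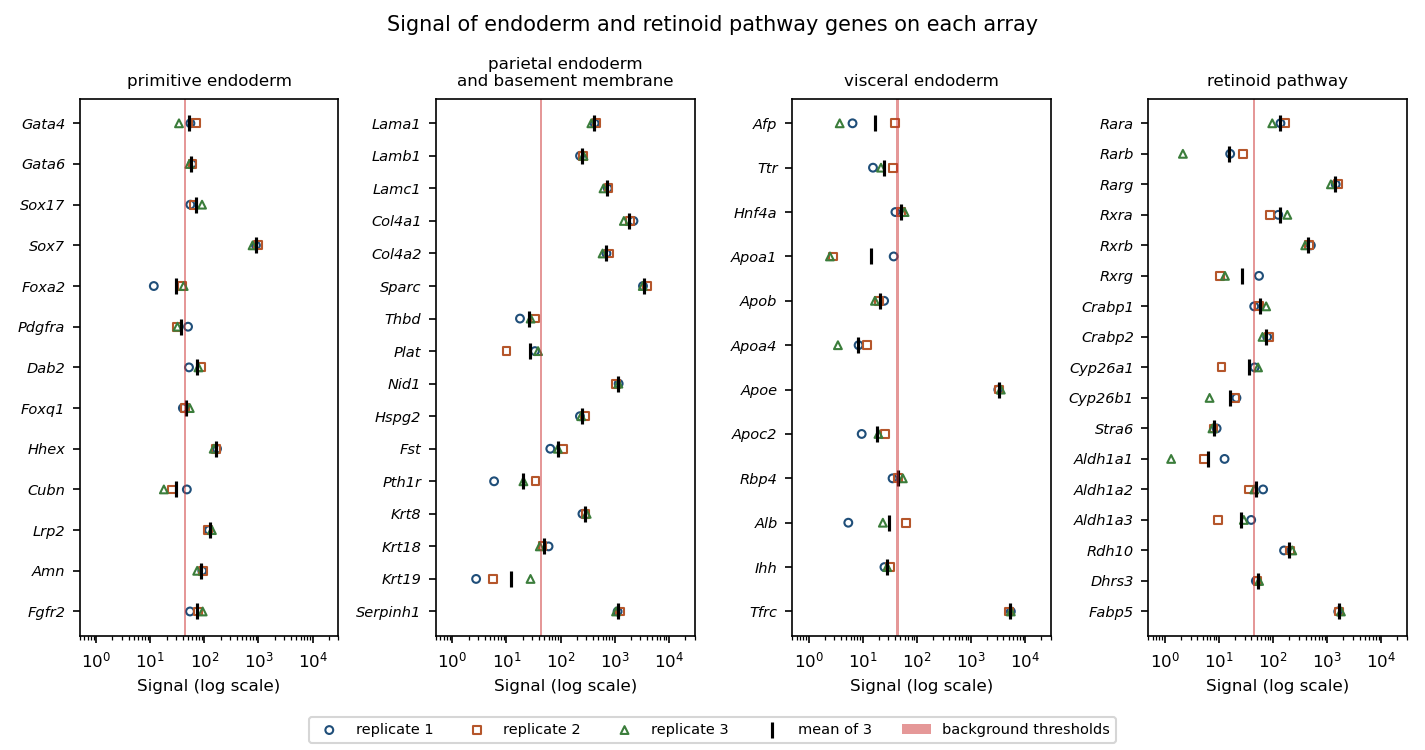
Each row is a gene of the 3 endoderm lists or the retinoid list, each open symbol its signal on 1 array (log scale), each black tick the mean, and the red band the range of background thresholds. Laminin, collagen IV and Sox7 signals lie right of the band on every array, whereas the means of Afp, Ttr, Rarb and the Cyp26 genes lie left of it.

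Mesoderm, neuroectoderm and Hox genes were sparsely represented. None of 14 mesoderm genes was above background by limma's test (Fisher's exact test, adjusted p = 0.000168), including Mixl1 (13.7 ± 8.17), Mesp1 (60.7 ± 12.2), Mesp2 (59.9 ± 17.2) and Tbx6 (17.0 ± 6.15); 1 of them had an unadjusted limma p under 0.05, and 2 exceeded the threshold on all 3 arrays. With the threshold from bacterial controls, chosen after the data were seen, 35.7% of the list passed and the call ended (adjusted p = 0.136). Of 14 neuroectoderm genes 2 passed (adjusted p = 0.013): Tubb3 (1048 ± 70.6), a neuronal tubulin, and Nes (74.4 ± 6.75), whose call was lost without replicate 1 or replicate 3 (limma adjusted p = 0.0769 and 0.063). Pax6 (46.2 ± 5.23), Sox1 (56.4 ± 6.36) and Neurog1 (40.0 ± 18.2) did not. With the probe set chosen by suffix the list's share was again 14.3%, but its call was lost (adjusted p = 0.0554). Of 33 Hox genes only Hoxa5 (230 ± 77.2) passed (adjusted p = 5.62e-08), from 1 of its 2 probe sets; without the _s_at and _x_at probe sets it lay at -2.17 log2 units. Hoxb1 (12.0 ± 12.2), Hoxb2 (17.0 ± 15.0), Hoxa2 (12.9 ± 7.40) and Hoxa3 (57.3 ± 40.2) did not.

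The trophoblast list had 4 of 14 members above background (Fisher's exact test, adjusted p = 0.143). These were Bmp4 (2410 ± 85.0), Eomes (470 ± 31.7), Tfap2c (136 ± 17.7) and Tead4 (106 ± 6.43), all of them known from other embryonic cells too. The trophectoderm factors Cdx2 (18 ± 14.1) and Elf5 (9.57 ± 8.82) were not above background. Germ cell genes passed in 11 of 16 cases (adjusted p = 0.249), among them Ddx4 (154 ± 17.0), Dazl (93.0 ± 4.54), Prdm1 (89.5 ± 19.9) and Ifitm1 (1508 ± 176); Prdm1 lost its call without replicate 1 or replicate 3 (limma adjusted p = 0.0957 and 0.101). Figla (32.9 ± 10.7), Piwil2 (41.6 ± 10.9) and the synaptonemal gene Sycp1 (13.7 ± 4.70) did not. Against matched random lists the germ cell share had an adjusted p of 0.048. The 2-cell embryo list had 1 of 8 above background, the translation factor gene Eif1a (2252 ± 178), and Tdpoz1, Tcstv1, Tcstv3 and Usp17la had mean signals of 5.06, 9.66, 14 and 14.8 (adjusted p = 0.0537).

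Fibroblast genes were above background in 4 of 15 cases (Fisher's exact test, adjusted p = 0.0958). Their share did lie below that of other genes, past the threshold, without the _s_at and _x_at probe sets. The same held with the bacterial controls, chosen after the data were seen. The 4 were Fn1 (1815 ± 109), Acta2 (115 ± 24.1), Thy1 (105 ± 17.3) and Vim (4605 ± 110), the last chosen after its values were seen. Acta2 lay at -3.48 log2 units without the _s_at and _x_at probe sets. The fibrillar collagens Col1a1 (22.0 ± 11.2), Col1a2 (39.3 ± 10.3) and Col3a1 (14.9 ± 8.19) were not above background.

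Genes of proliferation were expressed throughout. All 24 measured cell cycle genes were above background (Fisher's exact test, adjusted p = 1.83e-06), including the cyclins Ccne1 (1671 ± 542), Ccnd1 (629 ± 31.7), Ccnd2 (542 ± 38.9) and Ccnd3 (5319 ± 398). Of the CDK inhibitor and p53 target list 12 of 15 passed, including Cdkn1a (241 ± 32.0), Cdkn1b (715 ± 21.2) and Cdkn1c (102 ± 25.2). Cdkn1b lay at -1.01 log2 units with the probe set chosen by suffix. The INK4 inhibitor genes Cdkn2a (51.7 ± 14), Cdkn2b (35.5 ± 20.8) and Cdkn2c (27.1 ± 10.4) did not, whereas Cdkn2d (361 ± 16.2), another INK4 gene, chosen after its values were seen, did. That list's adjusted p was 0.0537, and 0.0319 to 0.0353 with any 1 replicate left out.

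DNA methylation and polycomb genes were above background in 19 of 20 cases (Fisher's exact test, adjusted p = 0.000168). The methyltransferases Dnmt1 (1943 ± 185), Dnmt3a (365 ± 47.3) and Dnmt3b (1236 ± 99.2) passed. So did Dnmt3l (1755 ± 107), a cofactor of Dnmt3a and Dnmt3b, and Tet3 (7.87 ± 0.800), with a single probe set, did not. All 13 glycolysis genes passed (adjusted p = 0.000761), among them Hk2 (1704 ± 28.0), Pkm (8858 ± 724), Ldha (10629 ± 483) and Slc2a1 (7717 ± 121). So did 17 of 17 ribosomal protein genes (adjusted p = 0.00011), such as Rpl4 (15578 ± 448), Rpl6 (13969 ± 556), Rps6 (792 ± 21.4) and Rps3 (13445 ± 742), though the Rps3 probe set preferred by suffix lay at -2.02 log2 units.

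Signalling genes of the FGF, BMP, Wnt and LIF pathways were above background in 18 of 24 cases, or 20 when adjusted over the list alone. They included Fgfr1 (285 ± 40.1) beside Fgf4, Bmp4 and Lifr, while Axin2 (61.3 ± 12.5), Fgfr2 (74.5 ± 19.4) and Fgfr3 (53 ± 45.6) did not pass. The share exceeded that of other genes (Fisher's exact test, adjusted p = 0.0422), but not against random lists matched on probe sets per gene (adjusted p = 0.319). Nor did it pass with the probe set chosen by suffix (54.2%, adjusted p = 0.333), without the _s_at and _x_at probe sets (70.8%, 0.0861) or with genes on several lists left out (75%, 0.0673). With any 1 replicate left out it was 70.8% (adjusted p from 0.0602 to 0.0666). Imprinted genes stood at 12 of 23 (adjusted p = 1): Peg3 (454 ± 49.5) and Mest (2110 ± 83.3) were above background, and Igf2 (57.6 ± 38.4), Snrpn (72.8 ± 53.6), Dlk1 (32.5 ± 3.30) and Ascl2 (35.6 ± 10.7) were not. Snrpn passed without replicate 2, at 1.25 log2 units (limma adjusted p = 0.0196). Of the X inactivation and Y chromosome list, Xist (263 ± 44.1) alone of 8 passed, on 1 of its 3 probe sets (adjusted p = 0.0537 for the share), and Eif2s3y (5.82 ± 3.92), Kdm5d (19.8 ± 19.9) and Uty (15.7 ± 10.2) did not.

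Of the 5 adult tissue lists, those of liver, photoreceptor, lymphocyte and muscle lay below other genes in their share above background, and the synaptic neuron list did not pass the test. None of 13 liver enzyme genes passed limma's test (Fisher's exact test, adjusted p = 0.000301), with Cyp2e1 at 15.6 ± 13.2, Tat at 10.5 ± 4.95, Cps1 at 42.3 ± 11.5 and Tdo2 at 50.01 ± 9.55; 0 had an unadjusted p under 0.05 and 0 exceeded the threshold on all 3 arrays. With the threshold from bacterial controls 46.2% passed (adjusted p = 0.451). Of 15 photoreceptor genes Gnat2 passed (69.1 ± 18.4; adjusted p = 0.00108 for the list), and of 13 lymphocyte genes Cd8a (70.9 ± 16.7; adjusted p = 0.00361). Not above background were the photoreceptor genes Gnat1 (5.65 ± 3.65), Pde6b (2.88 ± 1.4), Rom1 (28.5 ± 9.61) and Prph2 (3.27 ± 2.05) and the T cell genes Cd3e (7.20 ± 0.328), Cd4 (7.72 ± 4.33) and Cd3d (3.67 ± 0.425). Both single calls were lost when any 1 replicate was left out (limma adjusted p from 0.0945 to 0.133 for Gnat2 and from 0.0539 to 0.148 for Cd8a). Muscle genes passed in 2 of 16 cases (adjusted p = 0.0043): Mylpf, a fast skeletal myosin light chain gene, at 3166 ± 88.3, and Casq2 at 99.5 ± 4.74, whereas Ckm (45.4 ± 25.9), Myh6 (12.9 ± 2.17) and Acta1 (64.8 ± 17.1) did not pass. Of 14 synaptic neuron genes 5 passed (adjusted p = 0.328), with Stmn2 at 806 ± 13.7, Nefl at 109 ± 15.5, Syt1 at 70.8 ± 10.5 and Camk2a at 62.1 ± 6.60, and Syn1 (81.0 ± 26.1), chosen after its values were seen. Snap25 (11.7 ± 4.17), Gad1 (15.5 ± 11.3) and Slc17a7 (16.2 ± 4.89) did not pass. Without replicate 1 or without replicate 2 the list's share was 14.3% (Fisher's exact test, adjusted p of 0.0265 and 0.0259). Syt1 and Camk2a lost their calls with any 1 replicate left out, at up to 0.0981 and 0.153, and Syn1 without replicate 1 or replicate 2, at 0.154 and 0.143 (limma adjusted p). With the probe set chosen by suffix, Syt1 and Camk2a lay below the threshold.

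Spread between the 3 arrays was measured over the genes above background, a filter that favours agreement because limma's test uses the same arrays and genes with a wide spread tend to fail it. Over the 9253 genes above background the median SD of log2 signal was 0.122, and 55 genes (0.594%) differed by more than 2-fold between their highest and lowest array. Over the 10358 genes whose mean log2 signal exceeded the threshold, a set without that test chosen after the data were seen, the median SD was 0.134 and 310 genes (2.99%) differed by more than 2-fold. Between pairs of arrays, Pearson's r of log2 signal across the 9253 genes above background was 0.991 for replicates 1 and 2, 0.989 for 1 and 3, and 0.988 for 2 and 3 (Spearman's rho 0.990, 0.988 and 0.986). Over all probe sets it was 0.917 to 0.920. Genes are not independent replicates, so these values describe the arrays only. Without replicate 3 the median SD was 0.0812; 12 genes then differed by more than 2-fold, 16 without replicate 2 and 32 without replicate 1. Among the genes above background the widest was Samhd1, a dNTP hydrolase gene, with signals of 100, 540 and 118 on replicates 1, 2 and 3, a 5.39-fold range. Egfr (3.44-fold), Pskh1 (2.62-fold), Scly (2.59-fold) and Ddr1 (2.52-fold) followed, then Irak1, 3110021A11Rik, Nbeal1, Fgfrl1 and Sema6c with 2.47-fold to 2.49-fold. The mean signals of these 10 genes lay between 109 and 253. In 6 of them the signal came from a probe set ending in _s_at or _x_at, against 11.9% of all genes above background, and 9 of them, all but Sema6c, lost their call with at least 1 of the replicates left out (limma adjusted p from 0.0501 to 0.145). With the probe set chosen by suffix, Egfr, Sema6c and 3110021A11Rik lay below the threshold (log2 values of -2.60, -0.87 and -0.31).

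**Figure D4:**
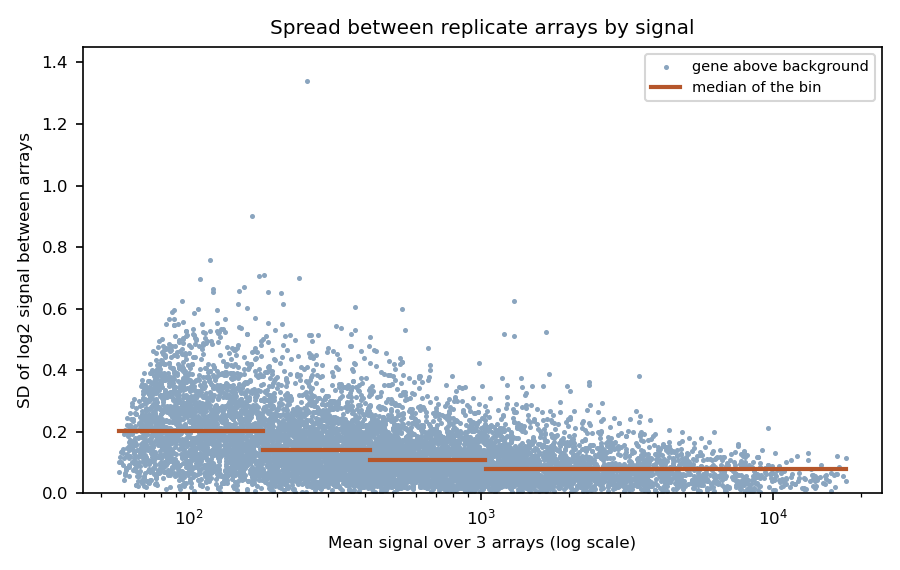
Each point is 1 of the 9253 genes above background, placed by its mean signal over the 3 arrays (log scale) and the SD of its log2 signal between them; lines mark the median SD in each of 4 equal bins of signal. The median SD falls from 0.202 in the lowest bin to 0.078 in the highest, and Samhd1 is the topmost point.

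The 3' and 5' parts of control transcripts built into the array are measured by different probe sets, so their ratios were compared between arrays and not between transcripts. The 3' to 5' signal ratio was 0.806 ± 0.011 (SD, n = 3) for Gapdh and 1.20 ± 0.0391 for beta-actin, against 0.946 and 1.23 for the 3' to middle ratio. For 2 further transcripts, chosen after their values were seen, it was 2.71, 2.70 and 1.98 on replicates 1, 2 and 3 for the transferrin receptor (2.46 ± 0.419) and 2.17, 1.91 and 1.74 for pyruvate carboxylase (1.94 ± 0.215). The hybridisation controls were bacterial and phage transcripts added in rising amounts. Their mean signals were 102 to 141 for BioB, 300 to 360 for BioC, 936 to 1223 for BioDn and 4070 to 5051 for CreX. Each of these means was lowest on replicate 1 and highest on replicate 3. Some further probe sets for the same transcripts did not follow that order, such as 1 for the 3' part of BioB (157, 158 and 150 on replicates 1, 2 and 3). Signal on the 18S ribosomal RNA probe sets was higher on replicate 1, 959, 578 and 620 for the 3', 5' and middle parts, which is 2.67, 2.18 and 1.85 times the mean of the other replicates.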

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

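The test in this part was chosen after the calls were made. Probe sets with several gene symbols or none, which enter no comparison of named genes, also carried signal: 1415 of 10092 (14%) were above background by limma's adjusted test, with a highest mean signal of 18996. No explanation was tested. With 3 arrays in 1 group, a single array far from the others was not tested for, and no contrast between groups exists to compare.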

How the results depend on the processing

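The background from bacterial controls and the set of genes with mean log2 signal over the threshold were chosen after seeing the data; the other alternatives were fixed before. Genes above background numbered between 7847 and 10718 over the alternatives. Core pluripotency genes exceeded the endoderm lists past the threshold in each (36.6 to 63.4 percentage points), which does not show that endoderm genes were low. Of the 27 lists, 15 kept their side of the threshold under every alternative, and 365 of 405 list results did. The exceptions follow as percent of the list above background with the adjusted p. At the 90th percentile the 2-cell embryo and X and Y lists passed at 12.5% (0.0469 each), as they did with the array median (12.5%, 0.046) and with all 3 arrays required above the threshold (12.5%, 0.0449). At the 99th percentile visceral endoderm no longer passed (16.7%, 0.072), while the CDK inhibitor (80%, 0.0186) and synaptic neuron (14.3%, 0.0473) lists did. With the probe set chosen by suffix, visceral endoderm (16.7%, 0.121), neuroectoderm (14.3%, 0.0554) and signalling (54.2%, 0.333) no longer passed, and the X and Y list did (0%, 0.0265). Without the _s_at and _x_at probe sets the fibroblast (20%, 0.037) and X and Y (0%, 0.00786) lists passed and signalling did not (70.8%, 0.0861). Against matched random lists primed epiblast (76.5%, 0.0454), germ cell (68.8%, 0.048), CDK inhibitor (80%, 0.0281) and X and Y (12.5%, 0.0388) lists passed and signalling did not (75%, 0.319), nor did it with genes on several lists left out (75%, 0.0673). With the bacterial controls visceral endoderm (33.3%, 0.121), mesoderm (35.7%, 0.136) and liver enzymes (46.2%, 0.451) no longer passed, and 2-cell embryo (12.5%, 0.0198), fibroblast (26.7%, 0.0295) and X and Y (12.5%, 0.0198) did.

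With 1 replicate left out, primed epiblast stood at 70.6% to 76.5%, visceral endoderm at 16.7%, CDK inhibitors at 80%, signalling at 70.8%, synaptic neuron at 14.3% to 21.4%, and naive over primed genes at 23.5 to 29.4 percentage points. The median SD was then 0.0812 to 0.108 and 12 to 32 genes differed over 2-fold; with 2 arrays a range is narrower by construction. With an offset of 16, which compresses low signals, 21 genes did. Over all genes with mean log2 signal over the threshold 310 did, because limma's test, which wide genes tend to fail, was left out. The Gapdh ratio was 0.946 with the middle probe set.

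Of 211 named genes, 154 had the same call under every alternative. Of the 2741 results for the 211 genes, 2599 kept their call, 70 lost it, 49 gained it and 23 changed sign. The last follow in log2 units over the threshold. Gata6 was at -0.022 at the 99th percentile. By suffix, 3110021A11Rik was at -0.31, Acta2 at -4.16, Camk2a at -0.82, Cdkn1b at -1.01, Egfr at -2.60, Fst at -0.34, Gata6 at -0.43, Hoxa5 at -2.17, Klf5 at -0.11, Rps3 at -2.02, Rxra at -2.97, Sema6c at -0.87, Syt1 at -0.67, Tbx3 at -0.17 and Xist at -3.70. Without the _s_at and _x_at probe sets, 3110021A11Rik was at -0.31, Acta2 at -3.48, Hoxa5 at -2.17 and Xist at -3.34. With the bacterial controls, Cps1 was at 0.86, Piwil2 at 0.84 and Psmb9 at 0.95. For changes that a higher or lower threshold, another probe set or fewer arrays do not bring by construction, the cause was not tested. No paired analysis was possible because there is only 1 group. The number of arrays and signals near background limit these calls.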

Other observations

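Gene families read from symbols were tested after the results for the fixed lists had been seen, 24 in all, with Fisher's exact test against other named genes and Benjamini-Hochberg adjustment. The proteasome, integrin and potassium channel families were narrowed after their values were seen, to drop symbols that only share the letters. Unlike the fixed lists, no family was set against random lists matched on probe sets per gene. Families of general cell machinery were above background nearly throughout: 76 of 76 mitochondrial ribosomal protein genes (adjusted p = 1.64e-21), 43 of 44 genes for complex I subunits and assembly factors (5.91e-11), 31 of 32 aminoacyl-tRNA synthetase genes (6.43e-08), 18 of 19 nuclear pore genes (0.00014) and 10 of 10 RNA polymerase II subunit genes (0.00299). In the proteasome family 43 of 47 passed (1.84e-08). The 4 that did not were Psmb8 (8.89 ± 9.44) and Psmb9 (44.1 ± 7.62), subunits of the immunoproteasome, Psmb11 (20.1 ± 15.2), the thymus form, and Psma8 (13.8 ± 4.01), the testis form. Psmb10 (225 ± 30.9), another immunoproteasome subunit, passed. The cytosolic chaperonin had 7 of 9 above background, all but Cct6b (2.50 ± 0.730) and Cct8l1 (27.2 ± 12.4), with an adjusted p of 0.197. Zfp zinc finger genes passed in 197 of 305 cases (5.07e-06).

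Families of differentiated or immune cells were mostly not above background. No protocadherin passed limma's test, 0 of 35 (adjusted p = 7.34e-11), and no beta-defensin, 0 of 20 (1.41e-06), with 0 and 0 genes at an unadjusted p under 0.05 and 0 and 0 over the threshold on all 3 arrays. Cytochrome P450 genes passed in 4 of 72 cases (5.64e-16), keratins in 4 of 44 (2.14e-08), interleukins in 1 of 28 (1.71e-07), voltage-gated potassium channels in 2 of 33 (1.20e-07) and chemokines in 3 of 31 (3.66e-06). Serpins (6 of 40, 6.35e-06), claudins (3 of 24, 0.000187), ADAM proteases (7 of 28, 0.00895), toll-like receptors (1 of 11, 0.0071) and Wnt ligands (3 of 19, 0.00299) were also under-represented. Cldn12 (1265 ± 57.4), Cldn4 (371 ± 31.4) and Cldn6 (97.6 ± 16.6) were the claudins above background. Integrins (8 of 26, 0.0578), kinesins (24 of 37, 0.117), frizzled receptors (6 of 11, 1) and Tudor domain genes (2 of 6, 0.462) did not pass the test.

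The tests of fibroblasts, of differentiated endoderm cells, of the 7 laminin, collagen IV, Sparc and Sox7 genes, of Y-linked probe sets, and of stress genes without the filter on calls, in the next 3 paragraphs, were chosen after the values had been seen; the others were written down before, but how to read the Xist count and the 99th percentile share was settled after their values were seen. Laminins, collagen IV, Sparc and Sox7 were above background in cultures described as undifferentiated, which could come from the stem cells or from other cells. Of 6 fibroblast matrix genes (Col1a1, Col1a2, Col3a1, Postn, Dcn and Lum), 0 were above background. Their median lay 1.70 log2 units below the threshold (a value of -1.70, SD 0.79 over genes). These 6 were picked after their values were seen, and the fibroblast list's called members Fn1, Vim, Acta2 and Thy1 were left out. The count therefore shows only that these matrix genes were not above background, and fibroblasts as a source stay open. Differentiated endoderm cells also stay open, and a small share of such cells may lie below detection. Of 10 other endoderm markers (Thbd, Plat, Pth1r, Krt18, Krt19, Gata4, Gata6, Foxa2, Dab2 and Pdgfra), 1 passed, Gata6. These 10 include all 5 uncalled members of the parietal list, so the count depends on the selection. Of the members left out, Krt8, Nid1, Hspg2, Serpinh1, Fst, Hhex, Lrp2 and Amn passed, and Sox17, Foxq1, Cubn and Fgfr2 did not. A low threshold was also considered. The 7 genes Lama1, Lamb1, Lamc1, Col4a1, Col4a2, Sparc and Sox7 all passed at the 99th percentile, the lowest by 2.10 log2 units (SE 0.24). That threshold was 68.1, 58.0 and 50.1 on replicates 1, 2 and 3, and the lowest gene, Lamb1, already lay 2.50 log2 units over the main threshold. Their passing was thus set in advance, and it shows only that these calls do not depend on the choice between the 2 percentiles. A low threshold stays open for the primitive and parietal lists as a whole. Of their called genes 13 of 16 (81.25%, exact binomial interval 54.4 to 96.0) still passed, all but Gata6, Amn and Fst. Expression by the undifferentiated cells themselves is a hypothesis that no group in this design tests.

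Xist was above background while none of the Y-linked genes on the fixed list was. Cross-hybridisation of a single probe set is a candidate explanation for Xist: 1 of its 3 probe sets passed, the one whose _s_at suffix marks shared sequence, at 263 ± 44.1, and the others stood at 3.45 ± 0.743 and 6.13 ± 6.05. Of 13 probe sets for 6 Y-linked genes (Eif2s3y, Kdm5d, Uty, Zfy2, Usp9y and Sry), 0 passed. Whether these probe sets can detect their transcripts cannot be told apart from a lack of transcript, because no array of a cell known to carry a Y chromosome was analysed here. No biological explanation was tested.

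Genes that differed between the arrays may do so for technical reasons. The median SD of log2 signal in the lowest of 4 equal bins of expressed genes by signal was 2.59 times that in the highest, and 40 of the 55 genes over 2-fold apart lay in the lowest bin, as low signal predicts. Growth and stress response genes that respond to culture handling were a second idea. The 11 such genes above background (Myc, Dusp1, Klf6, Atf3 and others) had a median SD of 0.0751 against 0.131 for random lists matched on signal, at percentile 1.69 of 10000 lists. Because limma's test tends to drop wide genes, the test was repeated without it: all 18 measured members had a median SD of 0.159 against 0.212 (percentile 10.49), and the 13 with mean log2 signal over the threshold 0.101 against 0.154 (percentile 4.69). Genes on that list thus did not spread more than matched genes. Whether culture handling played a part cannot be decided, because the labels do not say that the RNA came from separate cultures. The SDs of the 11 ran from 0.0197 for Myc to 0.282 for Hspa1a, whose call was lost without replicate 1 or replicate 2 (limma adjusted p = 0.0876 and 0.0783). Replicate 3 stood apart on the low side for 22 of the 55 genes, and no test of that array was made.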
